A study of Ovis aries with 6 samples.

How the data were processed

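The series holds 6 RNA-seq libraries of sheep (Ovis aries) ovary taken during estrus, 3 from Hu sheep and 3 from Mongolian sheep. Per the labels' protocols, RNA was collected with a column kit (RNeasy, Qiagen), 1 μg of total RNA went into each library, and libraries of polyadenylated RNA were made with a SMARTer kit. Sample groups and replicate numbers were taken from the sample titles, and the columns of the deposited tables were matched to samples by the column codes that the sample descriptions give. No column of the tables was left without a sample.

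The authors deposited a table of FPKM values for genes and a second table of FPKM values for lncRNAs, each with a column per library. The aligner, the counting tool, the genome build and any filter are not given in the sources used here. The identifiers show that the gene table holds 13359 Ensembl genes and 1121 genes assembled in the study, of which 10189 rows carry a symbol, and that the lncRNA table holds 170 Ensembl and 2285 assembled transcripts without symbols. The tables hold no coordinates, so no position is given for any gene or lncRNA, and no genome sequence was used. SMARTer kits copy RNA with template switching and amplify the copies by PCR, so values of scarce transcripts depend on how many molecules entered the library. FPKM divides by the library's total, so a transcript that takes much of a library lowers all others in it, and an absent transcript is listed at 0 whether it was missing or missed.

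Low values were examined for steps of whole reads. Among genes under 2 FPKM in both libraries of a pair, at most 0.655% shared a ratio within a bin 0.2% wide, so no value of a single read could be recovered, depth remained unknown, and no count model was used. No pair of libraries held an identical value above 0, so each library was counted as a separate sample.

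Genes with at least 0.5 FPKM in at least 3 of the 6 libraries (9971) were tested on log2(FPKM + 1), and lncRNAs with at least 0.1 FPKM in at least 3 libraries (417) on log2(FPKM + 0.1). A log2 difference on such a scale understates the change of low transcripts. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), two-sided, with breed as the only factor, all 6 libraries and Benjamini-Hochberg adjustment; a call is an adjusted p under 0.05. The tables were tested separately. An exploratory fit with the same settings came before the final script, and no setting of the tests was changed after it. Differences are Hu minus Mongolian.

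A set of 46 gene lists (cell types an ovary sample could hold, pathways of reproduction and growth, exosome proteins, and genes sensitive to RNA quality or handling) was written before the data were examined. The 36 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with a single row per symbol, and again with an estimated correlation, with fry and with ranks. With a preset correlation camera takes its degrees of freedom from the genes, and with an estimated one from the few libraries. The estimated setting therefore has little power over 36 lists. With a pseudocount of 0.1 camera called 5 lists, the 4 called otherwise and macrophage markers. The position of each list's median among 10000 random lists matched on mean level in 50 bins was also computed. Matched lists and members adjusted over the list alone are given beside the tests over all genes.

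Genes named in the text follow a rule fixed before the data were examined: the 12 largest changes in each direction past the threshold with a symbol, a mean of at least 1 FPKM in the higher breed and no overlap between breeds, or, where fewer than 5 pass, the 8 with the smallest unadjusted p under the same conditions; 22 genes of reproduction whatever their result; up to 4 members with the smallest p of each list described; and 6 lncRNAs in each direction, with a mean of at least 0.5 FPKM. As 0 genes and 0 lncRNAs passed, the second form of the rule was used in each direction. Of the genes it gave, 1 is not reported here. The housekeeping genes TBP and HPRT1, the 2 most abundant assembled genes and genes called only after libraries were left out were chosen after their values were seen. The collagen genes COL1A1 and COL3A1 were also named outside the rule.

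Alternatives fixed before the data were examined were other pseudocounts (0.1 and 0.01 for genes, 1 and 0.01 for lncRNAs), no filter, a filter at 5 FPKM for genes and 1 FPKM for lncRNAs, median-of-ratios scaling, quantile normalization, rescaling to a common sum per library, the replicate number as a block, other settings of eBayes, array weights, other thresholds and leaving out each library in turn. After the libraries were seen to differ in the number of genes listed, 3 more were added: only rows above 0 in all 6 libraries (5046 genes, 91 lncRNAs), Hu 1 and Hu 3 left out together, and the number of listed rows as a covariate. A planned comparison of lncRNAs with their neighbouring genes was not run, since the tables give no coordinates and the assembled lncRNAs have identifiers of their own.

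The fits were tested on simulated data with known changes. For limma these were placed only in genes and lncRNAs with a mean above the median. Residuals were shuffled row by row, so differences shared by a whole library were not kept. With the spread of the real libraries and 50 changed genes per size among 9971, limma recovered 0% of 2-fold, 2% of 4-fold, 28% of 8-fold and 76% of 16-fold changes, and called 3 unchanged genes. With 10 changed lncRNAs per size among 417 it recovered 0% at every size up to 16-fold. In a simulation with a list moved by 1.5 on the log2 scale, camera called that list and 0 others of 36. Residuals there were shuffled gene by gene, which removed the correlation between members of a list. That simulation therefore does not test how often camera calls lists whose members move together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.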

Results

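Ovarian RNA was profiled in ewes of a pair of sheep breeds during estrus, Hu sheep and Mongolian sheep, with 3 libraries per breed. Hu sheep are a Chinese breed known for large litters, and Mongolian sheep usually carry a single lamb, so the comparison asks which transcripts differ between ovaries of high and low prolificacy. The series title speaks of exosomes, whereas the label of every sample gives ovary as the source and polyadenylated RNA as the molecule, and the values below are described as ovary values. Expression was given as FPKM (fragments scaled by transcript length and library total) for 14480 genes and, in a separate table, for 2455 long noncoding RNAs (lncRNAs). Read counts were not used here, so the sequencing depth behind each value is unknown. Where 3 values are given for a breed they belong to replicates 1, 2 and 3 in that order. The labels do not say whether the replicates came from separate animals, and the p-values of single genes and lncRNAs measure only the spread between these libraries. Those of camera with a preset correlation compare a list's genes with all other genes, taken as nearly independent. They are therefore not evidence from replicate libraries alone.

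The Hu libraries differed strongly from each other in how many transcripts they listed. Genes above 0 FPKM numbered 6500, 7971 and 13342 in the Hu libraries and 10547, 11463 and 10606 in the Mongolian libraries. lncRNAs above 0 numbered 213, 332 and 1304 in Hu and 686, 725 and 789 in Mongolian. The number of listed genes was 9271 ± 3601 in Hu and 10872 ± 513 in Mongolian (mean ± SD, n = 3 each), a difference smaller than the spread within Hu (two-sided exact permutation test, p = 0.5; the smallest p that 3 against 3 libraries allow is 0.1). Genes that nearly all cells use were also listed at 0 in some libraries. TBP, the TATA-binding protein, stood at 0 in Hu 1 and at 1.98 FPKM or more in the other 5 libraries, and HPRT1, a purine salvage enzyme, stood at 0 in Mongolian 3 and Hu 1. A value of 0 is therefore described only as listed at 0. Between 53.3% and 79.7% of each library's summed gene FPKM lay in 2 assembled genes without a symbol, Ovis_arie_newGene_13259 and Ovis_arie_newGene_8186.

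**Figure D1:**
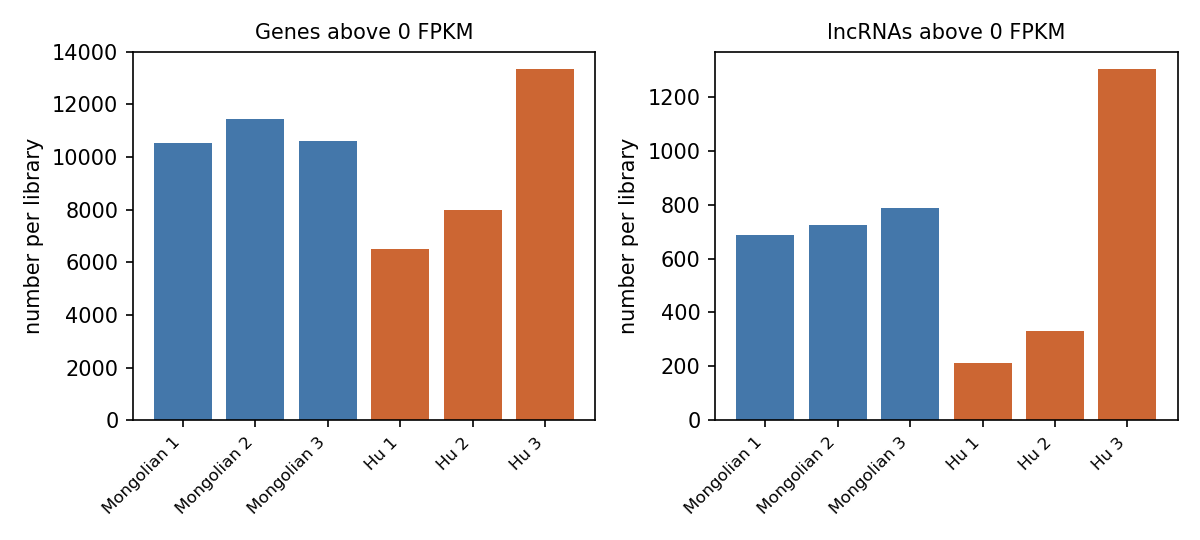
Number of genes (left) and lncRNAs (right) above 0 FPKM in each library, with Mongolian libraries in blue and Hu libraries in orange. Hu 1 and Hu 2 listed the fewest genes (6500 and 7971) and Hu 3 the most (13342), with the 3 Mongolian libraries between 10547 and 11463.

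Over genes, though not over lncRNAs, the Hu libraries resembled each other less than the Mongolian libraries did. Over the genes tested, Pearson correlations of log2(FPKM + 1) ranged from 0.69 to 0.75 within Hu (median 0.71), from 0.74 to 0.82 within Mongolian (median 0.76) and from 0.67 to 0.85 between breeds (median 0.73); these are correlations across genes, which are not independent replicates. Principal component 1 held 43.9% of the variance and placed Hu 1 (103), Hu 2 (40.6) and Hu 3 (-75.8) far apart, with the Mongolian libraries between them at -20.5, -19.6 and -27.8. Among lncRNAs the median correlation was 0.46 within Hu, 0.44 within Mongolian and 0.47 between breeds.

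The first comparison asked which genes differed between Hu and Mongolian ovaries. PLIN2, the protein that coats lipid droplets, averaged 32.0 ± 11.8 FPKM in Hu and 7.27 ± 4.08 in Mongolian (SD, n = 3 each), a log2 difference of 2.09 with a standard error of 0.59. SRP14, a component of the signal recognition particle, averaged 33.3 ± 15.9 in Hu and 6.16 ± 4.63 in Mongolian. ISLR, a secreted protein of stromal fibroblasts, averaged 1.33 ± 1.09 FPKM in Hu and 11.9 ± 1.68 in Mongolian, a log2 difference of -2.61 with a standard error of 0.69. None of these differences passed the threshold after adjustment for the 9971 genes tested: the limma adjusted p was 0.998 for PLIN2, SRP14 and ISLR, and the lowest of any gene was 0.117.

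Of the 9971 genes tested, 0 had a limma Benjamini-Hochberg adjusted p under 0.05, and 372 had an unadjusted p under 0.05 where 499 would be by chance alone. Of those 372 genes, 91 were higher in Hu and 281 lower. The direction of this split depended on the scaling between libraries: 24.5% of such genes were higher in Hu with the values as deposited, 28.7% after median-of-ratios scaling, 52% after quantile normalization and 51.3% after rescaling each library to a common sum. The median log2 difference over all genes tested was -0.28 as deposited, -0.23 after median-of-ratios scaling, 0.02 after quantile normalization, -0.17 after rescaling, 0.01 without Hu 1 and -0.66 without Hu 3, and 32.3% of all genes tested were higher in Hu as deposited. Medians of gene lists are therefore also given relative to the median of all genes. The median 95% confidence interval of a gene's log2 difference, unadjusted, reached 1.51 to either side. In a simulation with the spread of these libraries limma recovered 2% of 4-fold and 28% of 8-fold changes. Those changes were placed only in genes with a mean above the median, and residuals were shuffled gene by gene. All 3 Hu values lay above all 3 Mongolian values in 187 genes and below them in 603, together 7.92% of the genes tested, where chance alone gives 10%.

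The genes with the smallest unadjusted p were named by a rule that takes 8 in each direction, and none of the 16 passed the adjusted threshold. Among those higher in Hu, TOMM5, a subunit of the import channel of the outer mitochondrial membrane, averaged 30.6 ± 12.01 FPKM in Hu and 7.04 ± 5.44 in Mongolian. TCIM, a regulator of WNT signalling, averaged 19.6 ± 4.29 in Hu and 4.72 ± 1.36 in Mongolian. POLR3K, a subunit of RNA polymerase III, was listed at 0 in all 3 Mongolian libraries and at 4.69, 11.004 and 23.4 FPKM in Hu, and VAT1L was likewise listed at 0 in Mongolian and at 3.45, 3.01 and 4.97 in Hu. RARRES1, a gene induced by retinoic acid, stood at 14.1, 5.98 and 16.8 FPKM in Hu and at 0, 5.28 and 0 in Mongolian.

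Among the genes lower in Hu, 7 of the 8 were listed at 0 in Hu 2 and 6 of them also in Hu 1. PMVK, phosphomevalonate kinase of the cholesterol pathway, stood at 0, 0 and 1.36 FPKM in Hu and at 5.59, 7.08 and 7.46 in Mongolian. ANAPC11, a subunit of the anaphase-promoting complex, stood at 0, 0 and 2.99 in Hu and at 7.38, 13.7 and 9.60 in Mongolian. TNNI3, cardiac troponin I, stood at 0, 0 and 2.36 in Hu and at 8.81, 3.82 and 26.3 in Mongolian. ATP1B2, a subunit of the sodium-potassium pump, stood at 0, 0 and 4.93 in Hu and at 15.8, 8.38 and 7.93 in Mongolian. FBXL19 stood at 1.04, 0 and 1.33 in Hu and at 10.3, 4.39 and 10.8 in Mongolian. CCDC61 and the RNA helicase gene DDX51 were listed above 0 in Hu 3 alone among the Hu libraries, at 1.23 and 0.89 FPKM, and at 3.66 and 2.495 FPKM or more in every Mongolian library.

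**Figure D2:**
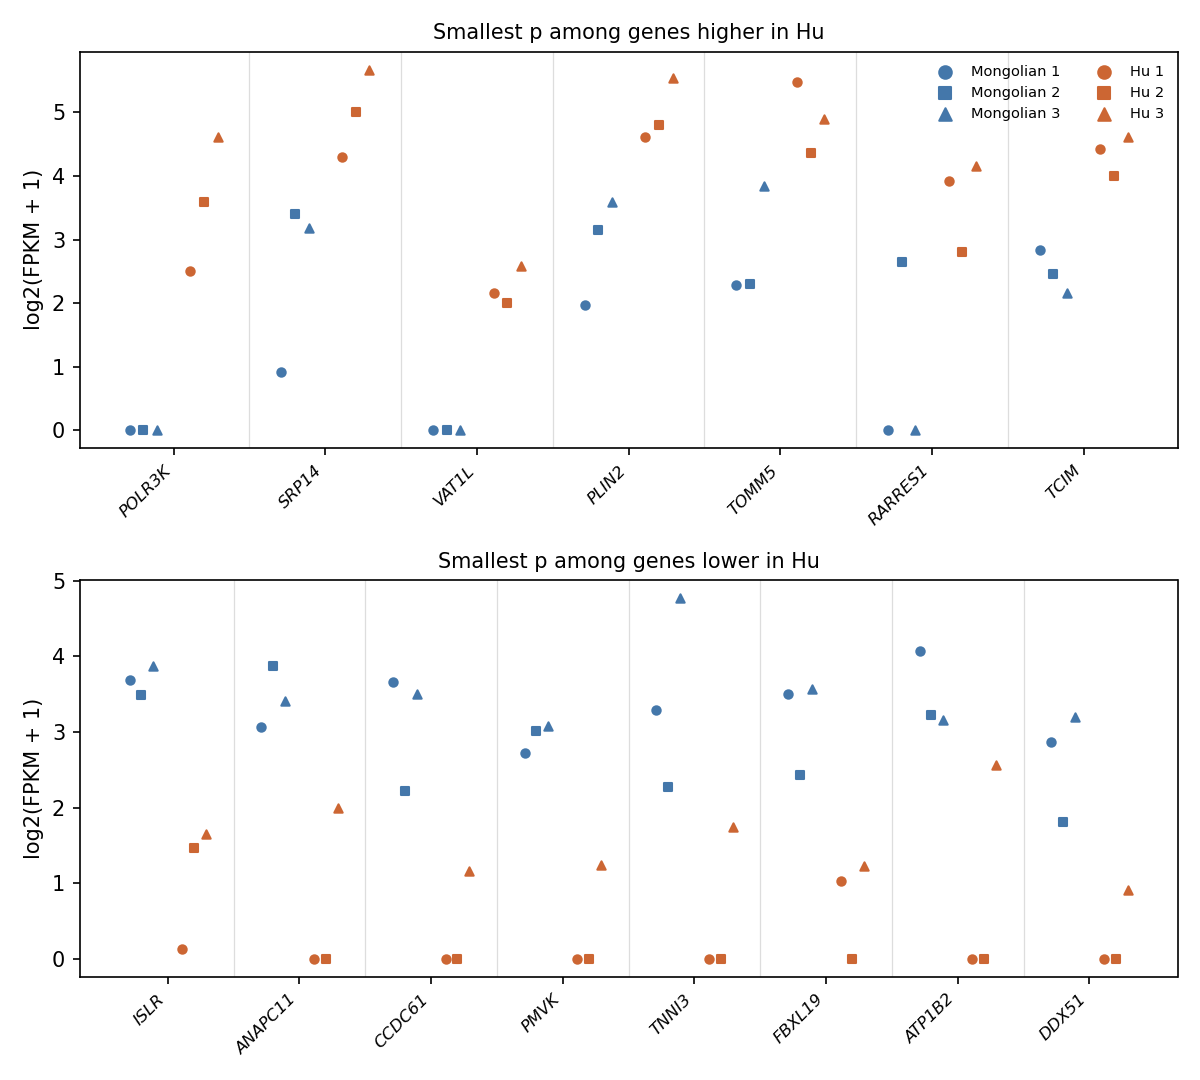
Expression as log2(FPKM + 1) of the genes with the smallest p that are reported here, 7 higher and 8 lower in Hu, with a point for every library (Mongolian in blue, Hu in orange, the replicate shown by the shape). POLR3K and VAT1L sit at 0 in all 3 Mongolian libraries, and 6 of the 8 genes in the lower panel sit at 0 in both Hu 1 and Hu 2; none of these genes passed the adjusted threshold.

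Among the alternative settings, weighting the libraries by their estimated quality, fixed in advance, gave the most calls and is not the result reported above: limma array weights gave 633 genes, 75 higher and 558 lower in Hu, with a weight of 3.64 on Hu 2 against 0.41 on Hu 1 and 0.25 on Hu 3. Without Hu 3 the genes at an unadjusted p under 0.05 numbered 1531, of which 4.25% were higher in Hu, and without Hu 1 they numbered 466, of which 64.8% were higher.

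Genes known from litter size, gonadotropin response and steroid synthesis were examined whatever their result. Of 22 such genes fixed in advance, 16 were listed by symbol and 12 were abundant enough to test. The lowest limma adjusted p of the 12 was 0.9978. BMPR1B, the bone morphogenetic protein receptor that carries the Booroola fecundity mutation, averaged 5.997 ± 5.31 FPKM in Hu and 4.38 ± 1.83 in Mongolian (n = 3 each), a log2 difference of 0.19 with a 95% confidence interval from -1.35 to 1.72. STAR, which delivers cholesterol to the mitochondrion for steroid synthesis, averaged 10.4 ± 7.45 in Hu and 3.61 ± 3.37 in Mongolian, a log2 difference of 1.35 (95% confidence interval from -0.20 to 2.90). FST, follistatin, which binds activin, averaged 4.76 ± 4.79 in Hu and 11.7 ± 3.73 in Mongolian, a log2 difference of -1.57 (95% confidence interval from -3.22 to 0.07).

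The inhibin subunit genes INHA and INHBA averaged 53.3 ± 42.4 and 41.8 ± 37.4 FPKM in Hu and 27.4 ± 12.4 and 15.8 ± 10.1 in Mongolian, with Hu 1 highest at 99.1 and 83.0. ESR1, an oestrogen receptor, averaged 11.1 ± 7.68 in Hu and 8.26 ± 1.51 in Mongolian. CYP11A1, the enzyme that cleaves the cholesterol side chain, averaged 14.1 ± 13.8 in Hu and 12.05 ± 14.8 in Mongolian. The steroid dehydrogenase HSD3B1 stood at 6.94, 0 and 11.2 FPKM in Hu and at 2.67, 1.99 and 41.3 in Mongolian, and CYP17A1, needed for androgen synthesis, at 0.62, 0 and 1.47 in Hu and 1.41, 0.79 and 0.08 in Mongolian. PGR, the progesterone receptor, stood at 0, 2.998 and 21.1 in Hu and at 2.31, 3.36 and 0.79 in Mongolian. VEGFA stood at 0, 0.75 and 2.88 in Hu and at 2.96, 0.57 and 16.2 in Mongolian, and FSHR, the follicle-stimulating hormone receptor, reached 0.95 FPKM at most in Hu and 1.95 in Mongolian. GDF9, LHCGR, ESR2 and PTGS2 were listed but under the filter, with LHCGR reaching 9.24 FPKM in Hu 3 and 2.69 in Mongolian 2. BMP15, B4GALNT2, CYP19A1, AMH, FOXL2 and IGF1 were not listed by symbol in the table used here, where 10189 of 14480 rows carry a symbol. The direction of BMPR1B, FSHR, ESR1, PGR and CYP11A1 turned without Hu 3, where their log2 differences were -0.39, -0.04, -0.27, -0.56 and -0.21, and that of HSD3B1 turned without Hu 2 or Mongolian 3, to 0.35 and 0.47. BMPR1B also turned without Mongolian 1 (-0.13), CYP11A1 without Mongolian 2 (-0.29), FSHR without Mongolian 1, Mongolian 2 or Hu 2 (-0.24, -0.24 and -0.19) and CYP17A1 without Mongolian 1 or Hu 2 (0.20 and 0.26).

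**Figure D3:**
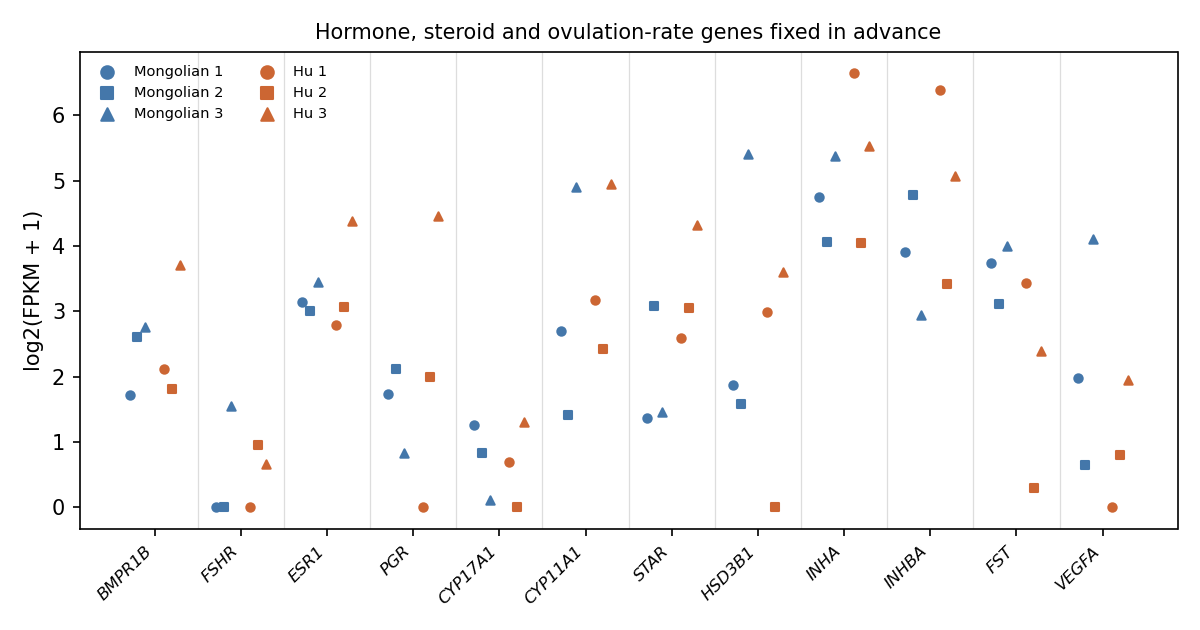
Expression as log2(FPKM + 1) of the 12 tested genes of reproduction fixed in advance, with a point for every library (Mongolian in blue, Hu in orange, the replicate shown by the shape). The points of both breeds overlap in all 12 genes, and Hu 3 is the highest Hu library for BMPR1B, ESR1, PGR and STAR.

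Gene lists were then compared between breeds, relative to all other genes tested. Genes of the mitochondrial genome had the smallest camera p: all 12 tested members had a positive log2 difference, with a median of 0.40, which is 0.68 above that of all genes (camera adjusted p = 0.00255 with a preset correlation of 0.01). The call was lost with an estimated correlation (adjusted p = 0.94 with an estimated correlation). CYTB, cytochrome b, stood at 284, 891 and 877 FPKM in Hu and at 28.9, 454 and 300.1 in Mongolian, ATP8 at 81.2, 427 and 423 in Hu and 166, 213 and 103 in Mongolian, ND3 at 24.5, 87.5 and 71.6 in Hu and 40.9, 69.7 and 13.03 in Mongolian, and ATP6 at 230, 648 and 950.2 in Hu and 406, 560 and 215 in Mongolian. As deposited, Hu 1 lay below the Mongolian mean in 11 of the 12 genes, and Hu 2 and Hu 3 both lay above it in 10. None of the 12 passed the test over all genes, and 0 passed adjusted over the list alone. The call was also lost without Mongolian 3, Hu 2 or Hu 3 (adjusted p = 0.395, 0.0943 and 0.0901), where the list lay 0.24, 0.475 and 0.54 above all genes, against 1.03 without Mongolian 2. It had 7 of 12 members higher in Hu without Mongolian 3, and 4 without Hu 3, where the median of all genes was -0.66. The list lay 0.305 above all genes after quantile normalization, 0.80 after median-of-ratios scaling (adjusted p = 0.000142) and 0.90 after rescaling to a common sum.

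Markers of ovarian stroma and its matrix were the next group called (camera adjusted p = 0.00445), with 15 of 19 members higher in Hu and a median log2 difference of 0.10, which is 0.38 above all genes. The call was lost with an estimated correlation (adjusted p = 0.778 with an estimated correlation). That correlation was 0.0103, close to the preset 0.01, so members moving together did not account for this loss. FN1, fibronectin, stood at 20.6, 25.7 and 16.2 FPKM in Hu and at 2.05, 8.94 and 13.5 in Mongolian, and POSTN, periostin, at 5.82, 4.32 and 7.69 in Hu and at 1.23, 2.10 and 2.21 in Mongolian. LUM, lumican, stood at 57.2, 62.5 and 114 in Hu and at 53.3, 54.2 and 20.1 in Mongolian. The fibrillar collagen genes COL1A1 and COL3A1 were close between breeds, with log2 differences of 0.10 ± 0.44 and -0.06 ± 0.42 (SE). Of the 19 members 0 passed the test over all genes or adjusted over the list alone. The call was also lost without Mongolian 1, Hu 1 or Hu 2 (adjusted p = 0.0536, 0.198 and 0.0943). The difference from all genes was 0.15 without Hu 1, 0.20 without Hu 2, 0.81 without Hu 3, 0.02 after quantile normalization, 0.50 after median-of-ratios scaling (18 of 19 members higher, adjusted p = 0.000147), 0.60 after rescaling to a common sum (19 of 19) and 0.14 with the number of listed genes as a covariate, a setting chosen after the data were seen.

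Markers of blood and lymphatic endothelium had a median log2 difference of 0.42, which is 0.70 above all genes, with 9 of 13 members higher in Hu (camera adjusted p = 0.0115). The call was lost with an estimated correlation (adjusted p = 0.94 with an estimated correlation). LYVE1, a lymphatic marker, stood at 1.61, 8.89 and 1.86 FPKM in Hu and at 0, 2.59 and 0 in Mongolian, PECAM1 at 5.23, 2.24 and 8.36 in Hu and 1.04, 2.32 and 0.91 in Mongolian, FLT4 at 1.60, 3.15 and 1.58 in Hu and 0.26, 1.42 and 0.93 in Mongolian, and VWF at 6.16, 2.38 and 4.72 in Hu and 2.87, 2.53 and 1.57 in Mongolian. None of the 13 passed the test over all genes or adjusted over the list alone. The call was also lost without Mongolian 1, Hu 1 or Hu 2 (adjusted p = 0.156, 0.198 and 0.0943), where the difference from all genes was 0.66, 0.41 and 0.70.

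Cytosolic ribosomal protein genes were called with a median log2 difference of 0.05, which is 0.33 above all genes, 26 of 46 members being higher in Hu and 20 lower (camera adjusted p = 0.0197). The call was lost with an estimated correlation (adjusted p = 0.94 with an estimated correlation). RPL10 stood at 83.6, 99.99 and 161 FPKM in Hu and at 95.9, 65.0 and 45.4 in Mongolian, and RPL37 at 60.3, 105 and 147 in Hu and at 53.4, 92.2 and 39.8 in Mongolian, whereas RPS28 stood at 87.6, 165 and 207 in Hu and at 233, 237 and 165 in Mongolian. None of the 46 passed the test over all genes or adjusted over the list alone. The difference from all genes was -0.11 after quantile normalization (19 of 46 members higher), 0.46 after median-of-ratios scaling (37 of 46, adjusted p = 8.84e-05), 0.55 after rescaling to a common sum (42 of 46), 0.05 without Mongolian 3 and 0.41 without Hu 3. Of the 46 members 39 were higher in Hu without Hu 1, but only 10 without Mongolian 3 and 9 without Hu 3. The call was also lost without Mongolian 3, Hu 2 or Hu 3 (camera adjusted p = 0.999, 0.0943 and 0.222).

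**Figure D4:**
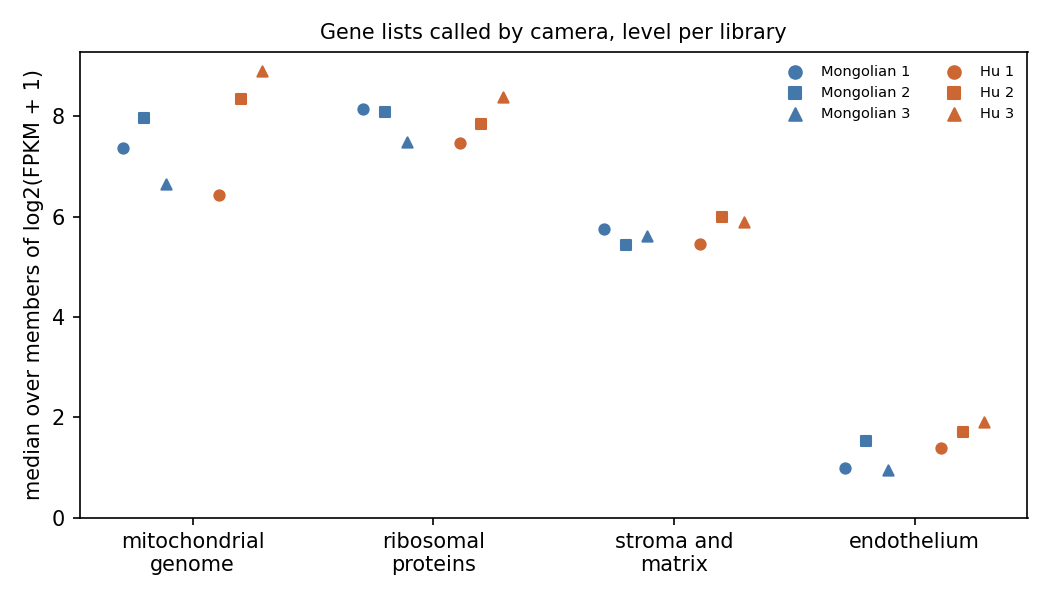
Level of the 4 gene lists called by camera in each library, as the median over the list's members of log2(FPKM + 1) (Mongolian in blue, Hu in orange, the replicate shown by the shape). Genes of the mitochondrial genome had a median of 6.43 in Hu 1 and of 8.35 and 8.90 in Hu 2 and Hu 3, against 6.64 to 7.97 in Mongolian.

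The remaining lists were not called by camera, and of their members 1 passed adjusted over its list alone. Of the 4 called lists and these 32, 0 were called with an estimated correlation or by fry, a rotation test of whether a list's genes move on balance to 1 side. Leaving out 1 library turned the side on which most members lay in 23 of the 32 lists, and the sign of the difference from all genes in 16. The side of most members also turned in 12 lists after quantile normalization, 8 after rescaling to a common sum and 2 after median-of-ratios scaling, and the sign of the difference in 2, 6 and 6. IGFBP3, which binds insulin-like growth factors in the circulation, stood at 0, 0 and 18.3 FPKM in Hu and at 11.4, 22.0 and 53.4 in Mongolian (limma adjusted p = 0.0493 adjusted over the list alone, 0.998 over all genes). In the insulin-like growth factor list 8 of 10 members were lower in Hu, with a median log2 difference of -0.29, which is 0.02 below all genes. In the list of litter size genes and the bone morphogenetic protein and TGF-beta signalling around them, 14 of 21 members were lower in Hu, with a median of -0.30, also 0.02 below all genes; the receptor gene BMPR1A stood at 0, 0 and 12.8 FPKM in Hu and at 13.6, 7.35 and 8.31 in Mongolian, and ID1, a target of this signalling, at 0, 0 and 6.94 in Hu and 11.7, 3.15 and 6.55 in Mongolian. The difference from all genes ran from -0.34 without Hu 1 to 0.20 without Hu 3 for the first of these lists, and from -0.17 without Mongolian 2 to 0.09 without Mongolian 1 for the second. Of the 21 members of the second, 12 were higher in Hu without Hu 1 and 4 without Hu 3.

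Markers of the steroid-making cells of the follicle and corpus luteum were not called. Of 13 granulosa cell markers 7 were higher in Hu and 6 lower, of 5 theca cell markers 2 were higher and 3 lower, and of 11 luteal markers 6 were higher and 5 lower, with camera adjusted p of 0.719, 0.875 and 0.128 and medians 0.30, 0.20 and 0.32 above all genes. The luteal list was called without Mongolian 3 (adjusted p = 1.68e-05), and without Mongolian 2 its adjusted p reached 0.564; with an estimated correlation and all libraries the adjusted p was 0.94. HSD17B1, the granulosa enzyme that makes oestradiol from oestrone, stood at 0, 0 and 0.63 FPKM in Hu and at 3.69, 2.46 and 6.52 in Mongolian, whereas HTRA1 averaged higher in Hu, at 23.8, 49.3 and 59.9 against 15.4, 29.5 and 8.67. OXT, oxytocin, which ruminant luteal cells secrete, stood at 78.6, 9.74 and 42.1 in Hu and at 0, 0 and 305 in Mongolian. Of 13 genes of steroid synthesis 5 were higher and 8 lower in Hu (median 0.15 above all genes), and FDX1, the electron donor of mitochondrial steroid enzymes, stood at 16.1, 6.55 and 27.2 in Hu and at 4.60, 4.69 and 3.34 in Mongolian. Of 15 genes of cholesterol synthesis 11 were lower in Hu, with a median log2 difference of -0.57, which is 0.29 below all genes (camera adjusted p = 0.132). It was called without Mongolian 2 (adjusted p = 0.0296), while with an estimated correlation and all libraries the adjusted p was 0.94, without Mongolian 3 it was 0.395 and over genes above 0 in all 6 libraries 0.631. Besides PMVK, INSIG1 stood at 0.82, 0 and 2.04 FPKM in Hu and at 6.38, 3.16 and 4.003 in Mongolian. Of these 15 genes, 8 were listed at 0 in Hu 1, 7 in Hu 2 and 0 in Hu 3. Genes induced before ovulation were split into 6 higher and 4 lower (median 0.40 above all genes), and hormone receptors into 4 higher and 7 lower (0.15 above). With 1 library left out, the difference from all genes ran from -0.01 (Hu 2) to 0.44 (Hu 3) for granulosa cells, from -0.31 (Mongolian 2) to 0.44 (Hu 2) for theca cells and from 0.04 (Mongolian 2) to 0.85 (Hu 2) for luteal cells. It ran from -0.13 (Mongolian 1) to 0.515 (Mongolian 3) for steroid synthesis, from -0.60 (Mongolian 2) to -0.08 (Mongolian 3) for cholesterol synthesis, from 0.225 (Hu 1) to 0.48 (Mongolian 3) for genes induced before ovulation and from -0.08 (Mongolian 3) to 0.28 (Hu 1) for hormone receptors. The side of most members turned for granulosa cells (5 of 13 higher) and luteal cells (4 of 11) without Mongolian 2, theca cells without Mongolian 1 (4 of 5), steroid synthesis without Hu 2 (8 of 13), genes induced before ovulation without Hu 3 (4 of 10) and hormone receptors without Hu 1 (7 of 11).

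Other cells and vessels of the ovary were measured by further marker lists. Of 15 smooth muscle and pericyte markers 9 were lower in Hu, with a median 0.19 above all genes; MYH11, smooth muscle myosin, averaged lower there, at 105, 110 and 176 FPKM against 224, 195 and 303 in Mongolian. Of 9 macrophage markers 7 were higher in Hu, with a median log2 difference of 0.42, which is 0.70 above all genes (camera adjusted p = 0.132, and 0.94 with an estimated correlation). This list was called with a pseudocount of 0.1 (adjusted p = 0.0429), without Mongolian 2 (0.000707) and without Hu 3 (0.0153), and without Mongolian 3 its adjusted p reached 0.837. Without Hu 2 only 3 of the 9 were higher, with a median of -0.08, which is 0.10 above all genes, against 1.13 above without Mongolian 2. Among its members CTSS stood at 0.84, 3.95 and 2.74 in Hu and at 0.12, 3.86 and 0.78 in Mongolian. Of 13 macrophage markers listed, those under the filter reached 0.1 FPKM only in Mongolian 2 and Hu 3, so they did not favour Hu. Of 17 angiogenesis genes 7 were higher and 10 lower (median 0.23 above all genes). Without Hu 1, 9 of the 15 smooth muscle markers and 11 of the 17 angiogenesis genes were higher in Hu. The difference from all genes ran from 0.04 without Hu 1 to 0.36 without Hu 3 for the former, and from 0.05 without Hu 2 to 0.26 without Hu 1 for the latter. Oocyte, surface epithelium, oviduct, T and natural killer cell, B and plasma cell, neutrophil and mast cell, red cell, nerve and adipocyte markers had too few tested members for a list test. Among them UPK1B, of the surface epithelium, stood at 3.005, 1.48 and 14.6 in Hu and at 1.05, 0 and 0.39 in Mongolian.

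Because the series is titled for exosomes, lists of exosome proteins were also described. Of 19 genes of proteins used as exosome markers 11 were higher in Hu and 8 lower (median log2 difference 0.05, 0.33 above all genes, camera adjusted p = 0.415), and of 31 genes of exosome formation and release 13 were higher and 18 lower (median -0.11, 0.17 above all genes, camera adjusted p = 0.719). Without Hu 3 only 5 of the 19 and 4 of the 31 were higher, and without Hu 1 16 and 19. The difference from all genes ran from 0.195 without Mongolian 1 to 0.37 without Hu 3 for the markers, and from -0.23 without Hu 3 to 0.195 without Mongolian 1 for formation and release. The tetraspanin gene CD82 stood at 0, 0 and 7.21 FPKM in Hu and at 5.71, 4.32 and 12.7 in Mongolian, and FLOT2 at 4.57, 3.46 and 17.8 in Hu and 19.8, 16.6 and 16.6 in Mongolian. CHMP1A, of the membrane-cutting ESCRT machinery, stood at 0, 0 and 7.11 in Hu and at 11.98, 7.41 and 8.40 in Mongolian, whereas VPS36 stood at 5.19, 5.29 and 11.8 in Hu and at 0, 2.05 and 2.18 in Mongolian. Of the 31 genes of exosome formation, 14 were listed at 0 in Hu 1, 9 in Hu 2 and 0 in Hu 3.

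The last comparison concerned lncRNAs. MSTRG.26925 was listed at 0 in all 3 Mongolian libraries and at 7.28, 7.50 and 33.6 FPKM in Hu, and MSTRG.19742 was listed at 0 in all 3 Hu libraries and at 9.07, 6.96 and 26.5 in Mongolian. These gave the lowest limma adjusted p of the table, 0.232, so neither passed the threshold. MSTRG.5602, MSTRG.26765, MSTRG.7183 and MSTRG.31766 were also listed at 0 in all Hu libraries and at 3.33, 1.65, 1.42 and 1.66 FPKM or more in every Mongolian library, and MSTRG.42186 stood at 0, 0 and 3.95 in Hu and at 8.65, 9.95 and 18.7 in Mongolian. Higher in Hu, MSTRG.8294 stood at 5.16, 2.72 and 10.3 against 0, 0.76 and 0, MSTRG.13716 at 3.06, 11.7 and 5.47 against 0, 2.81 and 0, and MSTRG.9657 at 8.62, 11.5 and 6.28 against 5.47, 5.85 and 0. MSTRG.42618 and ENSOARG00000026908 were lower in level, reaching 0.72 and 1.79 FPKM at most in Hu and 0.31 and 0.79 in Mongolian.

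Of the 417 lncRNAs tested, 0 had a limma adjusted p under 0.05 and 25 had an unadjusted p under 0.05, 3 higher and 22 lower in Hu, where 20.9 would be by chance. The median log2 difference was -1.01 on the log2(FPKM + 0.1) scale, and it depended on the scaling and on single Hu libraries: 0.09 after quantile normalization, -2.53 after rescaling to a common sum, -0.27 without Hu 1 and -1.75 without Hu 3. The share of higher lncRNAs among those at an unadjusted p under 0.05 moved from 12% as deposited to 52.4% after quantile normalization. All 3 values of the breeds did not overlap in 45 lncRNAs, 10.8% of those tested, where chance alone gives 10%. No lncRNA carried a symbol, so lncRNAs with established names could not be looked up.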

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

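The count of 0 called genes held in every alternative run except these: array weights gave 633, an unadjusted p under 0.05 with an absolute log2 difference of at least 1 gave 370, leaving out Hu 1 and Hu 3 together gave 6 (its lone Hu library is assumed to vary like the Mongolian ones, which give all the spread), and leaving out a single library gave 0 to 4 (2 without Hu 2, 4 without Hu 3). For lncRNAs the unadjusted threshold gave 25, and every other alternative, including each left-out library, gave 0. Rows above 0 in all libraries, Hu 1 and Hu 3 left out together and the covariate were chosen after seeing the data. The 4 called lists stayed called with rank-based camera and a pseudocount of 0.1, which added macrophages, but 0 were called with an estimated correlation or with fry, and 0 to 6 lists were called with a library left out (0 without Hu 2, 2 without Hu 1, 2 without Mongolian 1). With an estimated correlation the adjusted p was 0.778 for stroma and 0.94 for endothelium, mitochondrial genome and ribosomal proteins, and with fry it was 0.974 for all 4. The estimated correlation setting rests on few degrees of freedom, so its lack of calls does not show that no list differs. With a library left out the adjusted p ranged from 1.03e-05 to 0.198 for stroma, from 0.00719 to 0.198 for endothelium, from 9.55e-07 to 0.395 for the mitochondrial genome (0.395 without Mongolian 3, 0.0943 without Hu 2, 0.0901 without Hu 3) and from 0.0011 to 0.999 for ribosomal proteins, the last reversed without Mongolian 3. With Hu 1 and Hu 3 left out it was 0.126 for both endothelium and ribosomal proteins, and among genes above 0 in all libraries it was 0.252 for ribosomal proteins. The cause was not tested. Of 480 alternative log2 differences of the 40 named genes and lncRNAs, 18 reversed, in 7 genes, and 0 passed the threshold. PGR reversed with a pseudocount of 0.1 (-0.059) and 0.01 (-1.10), and CYP17A1 after quantile normalization (0.37) and rescaling to a common sum (0.0149). With a library left out the log2 difference ranged from -0.39 to 0.56 for BMPR1B, -0.24 to 0.54 for FSHR, -0.27 to 0.53 for ESR1, -0.56 to 1.67 for PGR, -0.39 to 0.26 for CYP17A1, -0.29 to 1.46 for CYP11A1 and -1.46 to 0.47 for HSD3B1. Same-numbered libraries did not deviate together (correlations of -0.01, -0.03 and -0.18 for genes, -0.01, -0.13 and -0.23 for lncRNAs). No pairing by number was thus seen, but with 3 libraries per breed these correlations cannot exclude it. With the replicate block 0 genes, 0 lncRNAs and 4 lists were called. The comparison of lncRNAs with neighbouring genes was not run.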

Other observations

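The patterns weighed here were picked after the calls had been seen, and the test of genes listed at 0 in every Mongolian library was chosen only after the result was seen. The reading of 2 tests was changed after their values were seen: splits with a sparse library on the absent side were no longer counted as evidence, and zeros above 20 FPKM were weighed beside those of the highest 20% of genes. For the test without Hu 3, 3 other readings were tried after its values were seen and dropped for the bound set before. By those readings 1, 2 or 3 of the 4 lists stayed open. Among the lists that camera did not call, enzymes of chromatin and DNA methylation were mostly lower in Hu, 19 of 22 with a median log2 difference of -0.60, which is 0.32 below all genes (camera adjusted p = 0.215). The list was called over genes above 0 in all 6 libraries, a setting chosen after the data were seen (adjusted p = 0.0226), while with an estimated correlation over all genes the adjusted p was 0.94. DNMT3A, which adds DNA methylation, stood at 4.09, 5.18 and 5.30 FPKM in Hu and at 11.1, 7.21 and 19.04 in Mongolian, and the acetyltransferase gene CREBBP at 4.94, 6.70 and 9.29 in Hu and 19.01, 8.51 and 19.2 in Mongolian. Genes of dividing cells were lower in 13 of 17 (median -0.62, 0.34 below all genes, adjusted p = 0.654), with MCM7, of the DNA replication helicase, at 0, 4.48 and 11.03 in Hu and 14.1, 10.2 and 14.0 in Mongolian, while CCNB1, cyclin B, went the other way at 3.31, 2.71 and 2.16 against 1.14, 0.38 and 0. Genes of glycolysis and hypoxia were lower in 17 of 19 (median -0.35, 0.07 below all genes, adjusted p = 0.558), WNT signalling in 10 of 13, NOTCH in 5 of 7, Hippo in 12 of 18 and PI3K and mTOR signalling in 12 of 20, with adjusted p of 0.558, 0.751, 0.719 and 0.558; against all genes their medians differed by -0.25, -0.04, -0.20 and 0.25. With 1 library left out, the difference from all genes ran from -0.44 (Mongolian 2) to -0.18 (Mongolian 3) for chromatin, from -0.71 (Hu 1) to 0.05 (Hu 3) for dividing cells, from -0.25 (Mongolian 2) to 0.34 (Mongolian 3) for glycolysis and from -0.36 (Mongolian 2) to -0.05 (Mongolian 3) for WNT. It ran from -0.33 (Hu 1) to -0.01 (Hu 3) for NOTCH, from -0.47 (Hu 3) to 0.10 (Hu 1) for Hippo and from 0.01 (Mongolian 3) to 0.37 (Mongolian 1) for PI3K and mTOR. Glycolysis had 10 of 19 members higher without Mongolian 3; without Hu 1, Hippo had 10 of 18, PI3K and mTOR 15 of 20 and chromatin 8 of 22. After quantile normalization 12 of 20 members of PI3K and mTOR signalling and 8 of 17 genes of dividing cells were higher, the latter list lying 0.04 below all genes.

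None of the stress and clearance lists was called. With all libraries and relative to other genes, camera placed all lists of this paragraph higher in Hu except antigen presentation. Nuclear genes of oxidative phosphorylation were lower in 14 of 22 (median -0.14, which is 0.14 above all genes, adjusted p = 0.719). AKR1B1, a prostaglandin F synthase of the ruminant reproductive tract, stood at 20.5, 24.8 and 26.8 FPKM in Hu and at 12.4, 10.3 and 7.72 in Mongolian, within a prostaglandin list split into 2 higher and 3 lower (adjusted p = 0.719). Complement genes were higher in 6 of 9 (adjusted p = 0.132), lysosome and autophagy genes in 12 of 21 (0.21) and matrix proteases in 11 of 21 (0.214). Genes of apoptosis were higher in 6 of 15 (0.751), endoplasmic reticulum stress in 5 of 12 (0.274), antioxidant enzymes in 10 of 21 (0.488), interferon-stimulated genes in 3 of 10 (0.875) and antigen presentation in 2 of 7 (0.719). With 1 library left out, the difference from all genes ran from -0.11 (Hu 3) to 0.37 (Hu 2) for oxidative phosphorylation, from -0.62 (Hu 3) to 0.70 (Hu 2) for prostaglandin, from 0.25 (Mongolian 3) to 0.84 (Mongolian 2) for complement, from 0.23 (Mongolian 3) to 0.55 (Mongolian 2) for autophagy and from 0.15 (Mongolian 1) to 0.53 (Hu 3) for proteases. It ran from -0.14 (Hu 2) to 0.15 (Hu 3) for apoptosis, from -0.03 (Hu 1) to 0.37 (Hu 3) for endoplasmic reticulum stress, from 0.04 (Hu 3) to 0.31 (Hu 1) for antioxidants, from -0.01 (Mongolian 2) to 0.23 (Mongolian 3) for interferon, from -0.43 (Mongolian 2) to -0.03 (Mongolian 3) for antigen presentation and from -0.07 (Hu 3) to 0.44 (Hu 2) for immediate early genes. Without Hu 1, 15 of 22 genes of oxidative phosphorylation, 9 of 15 of apoptosis and 17 of 21 antioxidant enzymes were higher in Hu, and without Hu 3, 3, 4 and 2. The side of most members also turned for autophagy without Hu 3 (8 of 21 higher), proteases without Mongolian 1 (8 of 21), and endoplasmic reticulum stress (7 of 12), immediate early genes (13 of 21) and prostaglandin (3 of 5) without Hu 2. Immediate early and heat shock genes were higher in 9 of 21 (0.719) with all libraries; HSPB1, a small heat shock protein, stood at 0, 0 and 179 in Hu and at 51.5, 86.6 and 77.9 in Mongolian. Without Hu 3, HSPB1 was among the 4 genes called lower in Hu, with CNBP, MXRA7 and ENSOARG00000019405, all of them listed at 0 in both Hu 1 and Hu 2; in Hu 3 the last 3 stood at 26.6, 43.7 and 136 FPKM, within or above their Mongolian values. Leaving out Hu 2 gave ENSOARG00000007930 as lower, although it stood at 87.8 FPKM in Hu 2 against 79.4, 37.6 and 33.7 in Mongolian and 0 in Hu 1 and Hu 3, and Ovis_arie_newGene_15404 as higher, the latter at 14218 FPKM in Hu 1, 0 in Hu 2, 8725 in Hu 3 and 0, 27.03 and 0 in Mongolian.

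Hu 1 and Hu 2 listed far fewer genes than Hu 3. If reads were short only for low genes, under 5% of the highest 20% of genes by level were to be listed at 0 in Hu 1; the share was 13.7%, against 0.21% in Hu 3. That bound was too strict, since these genes start at 6.78 FPKM: of genes averaging at least 20, 50 and 100 FPKM in the other libraries, Hu 1 listed 32 of 878, 2 of 314 and 0 of 166 at 0, and Mongolian 1 6 of 824, 2 of 298 and 1 of 161. From 20 FPKM the counts were 11 of 849 in Hu 2, 1 of 701 in Hu 3, 3 of 829 in Mongolian 2 and 2 of 810 in Mongolian 3. Hu 1 thus kept the highest share at that level, 3.64% against 1.3% in Hu 2 and at most 0.728% in the others. Shallow sampling or few starting molecules may thus be the source of the missing genes, and the values do not decide between them. A breed difference was not tested apart from these, as the Hu libraries lay on both sides of the Mongolian ones.

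The lists higher in Hu relative to other genes were tested against their level, because abundant genes are seldom listed at 0. The medians for stroma (percentile 85.56) and ribosomal proteins (47.25) lay within those of random lists of matched level. Abundance alone could thus account for both calls. Those for the mitochondrial genome (99.79) and endothelium (99.97) lay above them. The random lists drew each gene independently, whereas members of these lists moved together (estimated correlation 0.807 and 0.173). The test therefore cannot exclude abundance for the mitochondrial genome. Endothelial markers were low, with a median level of 1.23 on the log2(FPKM + 1) scale against 5.75 for stroma. Of the 13 members 5 were listed at 0 in Hu 1 and 4 in Hu 2. These values argue against high abundance as the source for endothelium. Without Hu 3, the difference from all genes was 2.14, 1.19, 1.23 and 0.797 times its full size for stroma, endothelium, ribosomal proteins and the mitochondrial genome. All lay above the bound of 0.5 set before. The median of all genes itself fell from -0.28 to -0.66 without Hu 3, which holds such differences up. The lists' own medians went from 0.10 to 0.15, 0.425 to 0.18, 0.054 to -0.25 and 0.40 to -0.115, in the same order. Only the stroma median did not fall, and for the others the bound cannot exclude Hu 3 as the source. On a score per library taken relative to the other genes, Hu 3 was the lowest Hu library for stroma, endothelium and ribosomal proteins. Hu 1 and Hu 2 each scored above every Mongolian library (lowest of the 2 against highest Mongolian 0.89 against 0.16, 0.53 against 0.26 and 0.37 against 0.28). The mean difference of their scores from Mongolian was 0.95 (95% confidence interval over libraries from 0.52 to 1.38), 0.61 (from -0.08 to 1.30) and 0.41 (from -0.75 to 1.58). List levels as deposited ran otherwise. Hu 3 was the highest Hu library for endothelium (1.92) and ribosomal proteins (8.39). Hu 1 lay below every Mongolian library for ribosomal proteins (7.48), and below Mongolian 1 for stroma (5.45 against 5.76). Only for stroma do the scores argue against Hu 3 alone, and only relative to other genes. For the mitochondrial genome Hu 2 (0.91) scored as high as Hu 3 (0.89). What was left without Hu 3 (0.54, from -1.55 to 2.62) rested on Hu 2 and on the low Mongolian 3 (-0.85). With means over members the interval for endothelium lay above 0 (0.80, from 0.12 to 1.48), while those of ribosomal proteins and the mitochondrial genome still held 0. The stroma interval lay above 0, but that list was picked after its call and abundance could account for it. After quantile normalization it lay only 0.02 above all genes. Whether Hu 1 and Hu 2 differ from Mongolian therefore stays open for every list. A difference between breeds, or in how much endothelium each piece of ovary held, also stays open, untested.

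POLR3K, VAT1L and ENSOARG00000006256 were listed at 0 in all Mongolian libraries and at 3 FPKM or more in all Hu libraries. Of the 18 directed splits that mix the breeds, 7 gave as many such genes and the highest gave 35. All 7 had Hu 1 or Hu 2, which list few genes, on the absent side, and the 3 splits with both on the present side gave 0, but these had Hu 3, which lists the most, on the absent side. The splits therefore decide nothing, and they cannot tell missed detection from absence for any of these genes.

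The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 0 genes, 0 lncRNAs and 4 lists, and the highest of the others 1 gene, 1 lncRNA and 6 lists. Of the 10 splits, 10, 10 and 5 gave results as large. For genes and lncRNAs this was fixed by the real count of 0 and decides nothing. At an unadjusted p under 0.05 the real split gave 372 genes, and 3 splits that set Hu 1 and Hu 2 against Hu 3 gave 1086, 1043 and 990, which points to a structure of the libraries other than breed.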
